A study of Homo sapiens with 12 samples.

How the data were processed

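RNA from cultured human endothelial cells was measured on 12 single-channel Affymetrix arrays, 6 for samples labelled as aortic and 6 for samples labelled as dermal endothelial cells. Per the labels' protocols, the cells were bought from a supplier, grown on gelatin in endothelial medium and detached with trypsin, and biotin-labelled probes were made from total RNA. The growth protocol calls the cells BMECs, an abbreviation it does not explain and that matches neither group name. The array design, from the probe table used here, is the Human Genome U133 Plus design. Each sample's group and replicate number came from its title.

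The deposited values are linear intensity values, 1 per probe set and array, and the authors had already summarised and scaled them. This was read from the values, which ran from 0.0598 to 66253 and had a mean of 500.1 on every array after the top and bottom 2% were left out. Per the submitters' processing notes, Affymetrix Expression Console, Transcriptome Analysis Console, RMA and Partek were used, with no role or order given. RMA gives log2 values, whereas the deposited intensity values are linear and their distributions differ between arrays. The step that made them is not given in the sources used here. Scaling every array to the same mean makes each gene's level relative to the other genes on its array, so a change in total RNA per cell cannot be seen. Dim probe sets were noisier on the log2 scale than bright ones, because no variance stabilisation is visible in the values.

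The table held 54675 probe sets, of which 62 were control probe sets. A symbol table for the array named 41097 probe sets with 1 gene symbol and 1801 with several, and 11721 probe sets other than controls had no name here. Of the probe sets with 1 symbol, 41043 matched a gene of the GRCh38.p14 annotation through their gene number, and 0 symbols needed an update. No coordinates were used, apart from the order of genes along chromosomes in that annotation for a search for neighbouring genes. Probe sets with several symbols named no gene. Genes of the Y chromosome and the transcripts of the X-inactivation centre were left out of every table and test. This left 54504 probe sets and 19732 genes. Where several probe sets named a gene, as for 10507 genes, the set with the highest mean over the 12 arrays stood for it. No filter on dim genes was applied in the main setting.

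Values were put on the log2 scale without a pseudocount. The background floor of an array was the 95th percentile of its 27 probe sets for Bacillus subtilis transcripts, which human RNA does not hold. A gene at or below the floor on all 6 arrays of a group was given only a bound there. Its fold was then the other group's mean over the mean of the floors, written as at least that many fold, and no fold was given where the other group's mean was under that level. After the data were seen, a bound was also given for genes above the floor on some arrays of a group whose mean log2 signal there was under the mean of the group's floors. This bound is the other group's mean over the mean of, per array, the higher of the floor and the gene's own signal, on the log2 scale. Signal over this background takes the place of read depth for arrays, and the number of arrays, 6 per group, limits the precision of each mean. Levels are given as mean log2 signal ± SD.

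Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Differences are the mean of the samples labelled aortic minus the mean of the samples labelled dermal. Before the data were examined, 34 gene lists were fixed, covering endothelial subtypes, regional transcription factors, matrix, signalling, metabolism, growth, stress and markers of other cell types. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 34 lists, and again with an estimated correlation, on ranks and with fry. The calls of members were also adjusted over the list alone. List genes that no probe set with 1 symbol measured, including 3 of 21 genes chosen to be always named, are not analysed here.

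The genes named in the text were fixed by a rule written before the data were examined. They are the 12 genes with the largest fold in each direction among those past the threshold whose groups did not overlap, passing over uncharacterised loci; the 3 members of each list with the largest difference past the threshold; and the 18 measured genes of the always-named set. This gave 117 genes, of which 114 were past the threshold. Any other gene named is said to have been chosen after its values were seen.

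Array measures (median signal, floor, share of genes above the floor, 3′ to 5′ ratios of the actin and GAPDH control probe sets, the ribosomal 18S control and the bioB and cre hybridisation controls) were compared with 2-sided exact permutation tests, adjusted over the 8 measures. With 6 arrays against 6, the smallest p that such a test can give is 0.00217. Arrays were also compared by Pearson correlation over all genes and by principal components of the 5000 most variable genes.

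Alternatives planned before the data were examined were the mean of all probe sets of a gene, every probe set as its own feature, quantile normalization, centring each array on its median, filters at the median and at the 25th percentile of mean signal, eBayes with trend and robust settings, array weights, the replicate number as a block, a test against a fold of 1.5 (treat), the samples numbered 1 to 3 or 4 to 6 alone, and leaving out each sample in turn. Raising values to the floor of each array, raising values on all arrays to the highest of the 12 floors, taking log2 of the signal plus 32, and leaving out dermal 5 and 6 were added after seeing the data.

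The scripts were tested on simulated data made from these 12 arrays, with 19732 genes in the comparison of aortic-labelled and dermal-labelled samples. True log2 changes of 0.5, 1 and 2 were recovered for 25.4%, 49.3% and 78.8% of 67, 67 and 66 genes. At a change of 1, recovery was 96.6% for bright and 13.2% for dim genes, so a missing call for a dim gene says little. Of the 107 simulated calls, 4.67% were false. The real comparison called 7160 genes, so its adjustment was less strict, and these shares may understate recovery there. The software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.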

Results

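The series set cultured human aortic endothelial cells, which line the largest artery, beside dermal endothelial cells from the vessels of the skin, to ask how their gene expression differs. The cells were bought from a cell supplier, and whether they were primary or immortalised is not given in the sources used here. Each group had 6 samples. The labels do not say whether the 6 samples of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Lists of lymphatic and capillary genes were higher in the samples labelled aortic, so the groups are called aortic-labelled and dermal-labelled throughout, and every direction below rests on those labels.

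The arrays separated by group. Pearson correlations over all genes lay between 0.955 and 0.959 within the aortic-labelled samples, between 0.955 and 0.959 within the dermal-labelled samples, and between 0.934 and 0.939 across groups. The first principal component held 27.0% of the variance and separated the groups, and the next components held 8.31% and 8.07%. No array was a copy of another. On each array 68.4% to 78.6% of genes lay above the background floor, with 11619 genes above it on all 12 arrays and 1971 on no array. Some array measures differed between groups as well. The median signal was 85.6 ± 6.16 in aortic-labelled and 73.2 ± 2.64 in dermal-labelled samples (exact permutation p = 0.00217, adjusted p = 0.00577; SD, n = 6 each). The floor was 47.5 ± 11.1 against 33.9 ± 5.36 (exact permutation p = 0.026, adjusted p = 0.0416), and the 18S ribosomal control signal was 4769 ± 850 against 2591 ± 271 (exact permutation p = 0.00217, adjusted p = 0.00577). The bioB hybridisation control was 1178 ± 87.6 against 1048 ± 29.9 (exact permutation p = 0.00217, adjusted p = 0.00577) and the cre control 35520 ± 2368 against 32120 ± 1605 (exact permutation p = 0.0152, adjusted p = 0.0303). The actin 3′ to 5′ ratio, which rises with RNA degradation, was 1.87 ± 0.0696 against 2.22 ± 0.527 (exact permutation p = 0.178, adjusted p = 0.237), with dermal 5 at 3.01 and dermal 6 at 2.72. Some measures were close in samples 1 and 2, 3 and 4, and 5 and 6 of a group. The 18S signal of aortic 1 to 6 was 5842, 5842, 4530, 4306, 4049 and 4045. The actin ratio of dermal 1 to 6 was 1.82, 1.66, 2.07, 2.04, 3.01 and 2.72. The floors of aortic 1 to 6, at 40.8, 58.5, 55.9, 35.9, 58.0 and 36.0, did not pair in this way. Whether such pairs were handled together is not given, and no fit took them as blocks. Each group may thus hold fewer than 6 independent samples.

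The lists with higher signals in aortic-labelled cells included those of lymphatic and capillary endothelium, HOX paralogues 1 to 8, interstitial and basement membrane matrix, and leukocyte adhesion and chemokines. The cell cycle and cholesterol synthesis lists were higher in dermal-labelled cells. Of 19732 genes, 7160 passed the adjusted threshold (36.3%), 3770 higher and 3390 lower in aortic-labelled cells. Of these, 1004 were higher and 607 lower by 2-fold or more, and in 61 of these 1611 genes both groups were at background. With only genes above the median of mean signal tested, 324 were higher and 362 lower by 2-fold or more. The groups did not overlap in any sample for 5166 genes (26.2%), against 0.216% by chance. The balance of directions depended on scaling: 52.7% of called genes were higher in aortic-labelled cells as deposited, 48% after quantile normalization, 31.5% with each array centred on its median and 69.3% with values raised to the floor. These alternatives moved the median of all genes, 0.09 on the log2 scale as deposited, by -0.1, -0.16 and 0.16.

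**Figure D1:**
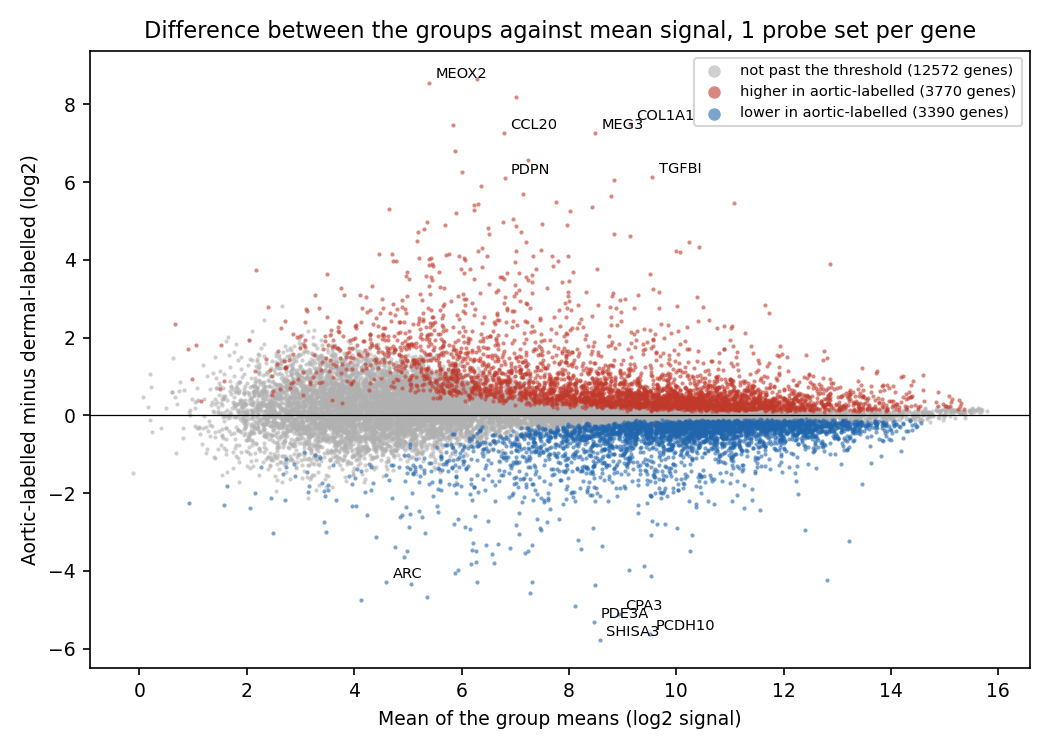
Difference between group means (aortic-labelled minus dermal-labelled, log2, vertical) against the mean of the group means (log2 signal, horizontal), 1 point per gene, 6 samples per group. Coloured points are the 3770 genes higher and the 3390 lower past the adjusted threshold; genes of low signal spread most, and differences there passed the threshold less often.

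COL1A1, which encodes the main chain of type I collagen, had the largest difference among those of the 12 leading genes that were above the floor on at least 1 array of each group. Its log2 signal was 12.9 ± 0.0995 in aortic-labelled and 5.39 ± 0.388 in dermal-labelled cells, 181-fold (log2 difference 7.50, SE 0.16, adjusted p = 3.39e-11; SD, n = 6 each, above the floor on 5 of 6 dermal-labelled arrays). The long noncoding RNA MEG3 was at least 114-fold higher (adjusted p = 1.06e-08), with 2 of 6 dermal-labelled arrays above the floor. TGFBI, a matrix protein induced by TGF-beta, was 69.6-fold higher (adjusted p = 3.69e-10), and the steroid dehydrogenase HSD17B2 was 66.2-fold higher (adjusted p = 4.13e-11). The lymphatic surface glycoprotein PDPN was at least 26.3-fold higher (adjusted p = 4.52e-07), with 1 of 6 dermal-labelled arrays above the floor. For 7 of the 12 genes that lead in this direction, the dermal-labelled arrays were all at background. ADRB1, the beta-1 adrenergic receptor, was at least 46.9-fold higher, SNHG24 at least 43.9-fold, the chemokine CCL20 at least 40.8-fold, and the homeobox factor MEOX2 at least 24.5-fold. The desmosomal protein DSP was at least 22.7-fold higher, the glypican GPC5 at least 18.8-fold and the G protein subunit GNG2 at least 18.4-fold.

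In the other direction SHISA3 led, at 11.5 ± 0.0776 in dermal-labelled and 5.70 ± 0.403 in aortic-labelled cells, 54.6-fold (adjusted p = 2.94e-10; SD, n = 6 each). The protocadherin PCDH10 was 49.4-fold higher in dermal-labelled cells, the phosphodiesterase PDE3A 40.1-fold, the carboxypeptidase CPA3 34.4-fold and the transcription factor TFAP2A 29.9-fold. DOK5 was 20.7-fold higher, PCDH7 at least 15.6-fold and the peptide receptor VIPR1 at least 6.69-fold. Of the 6 aortic-labelled arrays, 4 were above the floor for SHISA3, PDE3A and TFAP2A, but only 1 for PCDH7 and 1 for VIPR1. Aortic-labelled arrays were all at background for RGS7BP, the kinase LRRK2, the activity-regulated gene ARC and the divergent transcript PCDH10-DT, which were at least 4.44-fold, 3.25-fold, 2.30-fold and 1.94-fold higher.

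Both groups carried strong endothelial signal. PECAM1, an adhesion molecule of all endothelium, stood at 15.2 ± 0.0803 and 15.0 ± 0.0542 in aortic-labelled and dermal-labelled cells, VWF at 15.2 ± 0.109 and 14.9 ± 0.0527, and the junctional cadherin CDH5 at 14.0 ± 0.0455 and 13.8 ± 0.037 (SD, n = 6 each). These differences of 0.25, 0.25 and 0.27 passed the threshold as deposited, but not with arrays centred on their median (adjusted p = 0.312, 0.342 and 0.135), and PECAM1 turned to -0.02 with the mean of its probe sets. Of 27 pan-endothelial genes, 8 were higher, 10 lower and 9 not past the threshold; adjusted over the list alone, 8 were higher and 12 lower. The list median of -0.05 turned positive after quantile normalization, and the list test gave an adjusted p of 0.446. The nitric oxide synthase NOS3 was 2.80-fold lower in aortic-labelled cells (adjusted p = 2.04e-05) and CLEC14A 1.74-fold lower, whereas the TGF-beta co-receptor ENG was 1.59-fold higher. With the mean of all probe sets, NOS3 and ENG no longer passed (adjusted p = 0.222 and 0.162).

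Lymphatic genes were higher in aortic-labelled cells. Of 24 members, 15 were higher, 2 lower and 7 not past; adjusted over the list alone, 16 were higher and 2 lower (list median 1.58, camera adjusted p = 6.51e-06). PROX1, the transcription factor that sets lymphatic identity, stood at 8.66 ± 0.121 against 5.89 ± 0.626, 6.84-fold higher (adjusted p = 3.67e-06; SD, n = 6 each). TBX1 was 25.3-fold, the secreted glycoprotein RELN 18.8-fold and the VEGF-C receptor FLT4 3.93-fold higher. LYVE1, the hyaluronan receptor of lymphatic vessels, differed by 0.25 (adjusted p = 0.0102), which did not pass with arrays centred on their median (adjusted p = 0.403). Of 23 capillary and microvascular genes, 13 were higher, 3 lower and 7 not past; adjusted over the list alone, 14 were higher and 3 lower (list median 0.72, adjusted p = 0.000405). Beside MEOX2, these included MEOX1 (at least 18.1-fold, with 3 of 6 dermal-labelled arrays above the floor), the fatty acid transporter CD36 (at least 18.4-fold, likewise 3 of 6) and the fatty acid binding protein FABP4, at 14.8 ± 0.119 against 10.9 ± 0.18 (14.8-fold, adjusted p = 5.29e-11; SD, n = 6 each).

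Arterial genes went both ways. Of 25 members, 8 were higher, 9 lower and 8 not past, and the counts of 8 and 9 were the same adjusted over the list alone; the list test gave an adjusted p of 0.992, and the median of 0.04 turned negative after quantile normalization and with arrays centred on their median. HEY2, a Notch target that marks arteries, was at least 5.70-fold lower in aortic-labelled cells, at 4.80 ± 1.35 against 8.13 ± 0.326 (adjusted p = 0.000421; SD, n = 6 each), with 2 of 6 aortic-labelled arrays above the floor. SEMA3G was 5.43-fold and IGFBP3 4.49-fold higher. The arterial ligand EFNB2 differed by 0.08 (adjusted p = 0.18), a difference that turned negative with arrays centred on their median and passed after quantile normalization (0.13, adjusted p = 0.0441). The gap junction gene GJA5, above the floor on 1 array of each group and with both means under it, did not pass (adjusted p = 0.0922). It passed without aortic 2 (adjusted p = 0.0383) and with values raised to the floor of each array (adjusted p = 0.0157). The latter says nothing of GJA5, since it mostly compares the floors, which were higher on aortic-labelled arrays (47.5 against 33.9). Of 13 venous genes, 7 were higher, 2 lower and 4 not past; adjusted over the list alone, 8 were higher and 2 lower (list median 0.49, adjusted p = 0.0935). ADGRG6 was 8.34-fold and the venous receptor EPHB4 1.41-fold higher. The venular chemokine receptor ACKR1 was at least 1.39-fold higher. CPE, above the floor on 1 array in all, stood at 4.57 ± 0.983 against 2.83 ± 1.2 (adjusted p = 0.0412; SD, n = 6 each). CPE did not pass after quantile normalization (adjusted p = 0.0771), with arrays centred on their median (adjusted p = 0.0578), with log2 of the signal plus 32 (adjusted p = 0.0649) or in 9 of 12 fits that each left out 1 sample (adjusted p = 0.0528 to 0.087).

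**Figure D2:**
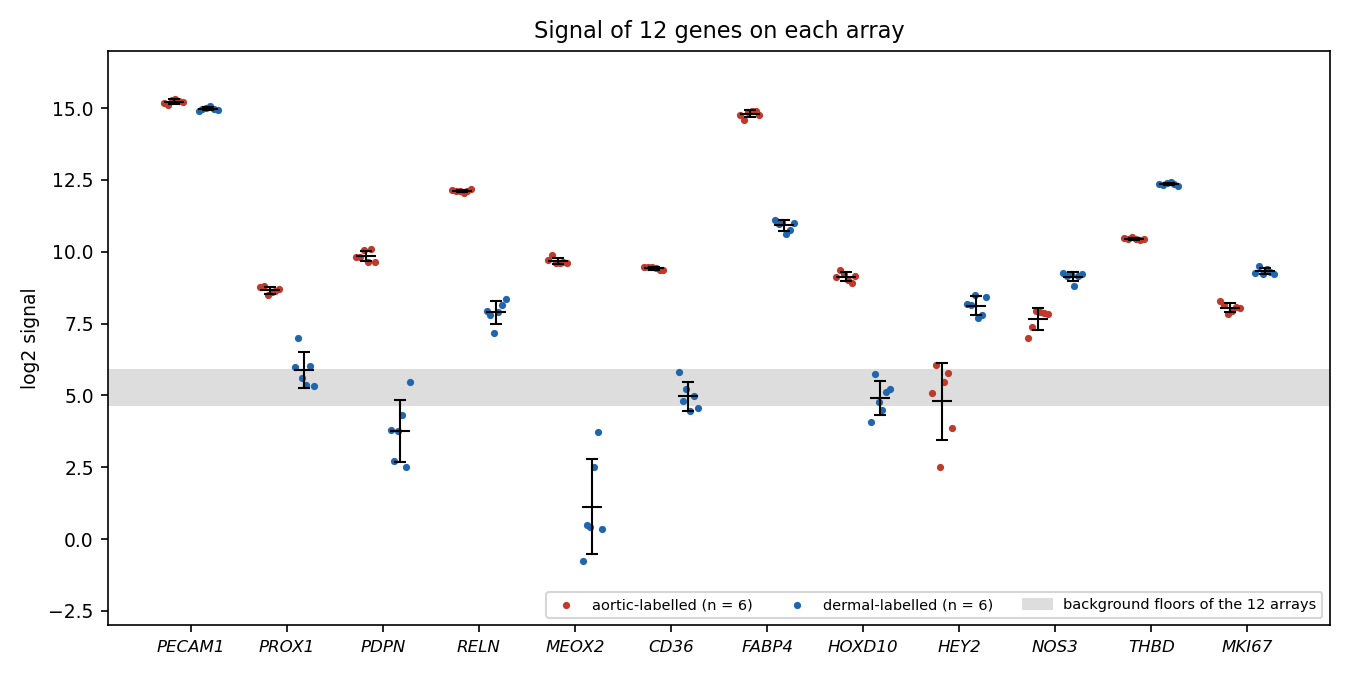
Log2 signal (vertical) of 12 genes (horizontal) on each of the 6 aortic-labelled and 6 dermal-labelled arrays, as points, with the group mean and SD as black bars and the range of the 12 background floors as a grey band. PECAM1 lies near 15 in both groups, the lymphatic, capillary and HOXD genes lie higher in aortic-labelled samples, and HEY2, NOS3, THBD and MKI67 lie higher in dermal-labelled samples.

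HOX genes, which record position along the body axis, were higher in aortic-labelled cells for paralogues 1 to 8. Of these 16 genes, 9 were higher, 3 lower and 4 not past; adjusted over the list alone, 10 were higher and 3 lower (list median 0.97, adjusted p = 0.00335). HOXD1 was higher by 5.25 on the log2 scale, HOXD4 at least 20.4-fold and HOXB8 at least 16-fold, with 5, 3 and 2 of 6 dermal-labelled arrays above the floor. For paralogues 9 to 13, 4 of 12 were higher, 0 lower and 8 not past, with the same counts adjusted over the list alone (list median 0.53, adjusted p = 0.0608). HOXD10 was at least 14.7-fold, HOXD9 at least 12.8-fold and HOXD13 at least 2.16-fold higher, with 3, 2 and 1 of 6 dermal-labelled arrays above the floor. Among 41 other regional transcription factors, 6 were higher, 9 lower and 26 not past, with the same 6 and 9 adjusted over the list alone; the list median was 0.29 while the list test pointed lower (adjusted p = 0.801). FOXF1 was at least 8.24-fold (4 of 6 dermal-labelled arrays above the floor) and TBX3 7.24-fold higher, whereas TWIST2 was 8.27-fold lower, with 4 of 6 aortic-labelled arrays above the floor.

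Matrix genes were higher in aortic-labelled cells. Of 35 interstitial and elastic matrix genes, 18 were higher, 4 lower and 13 not past; adjusted over the list alone, 19 were higher and 4 lower (list median 0.58, adjusted p = 2.7e-05). COL6A3 was 50.3-fold and the proteoglycan VCAN 41.3-fold higher, while periostin, POSTN, was 18.9-fold lower (14.9 ± 0.0986 in dermal-labelled cells; SD, n = 6). Of 21 basement membrane genes, 14 were higher, 2 lower and 5 not past; adjusted over the list alone, 15 were higher and 2 lower (list median 0.75, adjusted p = 0.00029). The collagens COL4A6 and COL4A5 were 6.54-fold and 4.92-fold higher, and nidogen NID2 was 5.39-fold lower. Of 15 fibroblast markers, 7 were higher, 2 lower and 6 not past; adjusted over the list alone, 8 were higher and 2 lower (adjusted p = 0.00941, and adjusted p = 0.0874 with an estimated correlation). COL1A1, COL6A3 and FAP (at least 9.54-fold, with 2 of 6 dermal-labelled arrays above the floor) led, and 8 of the 15 are also in other lists. Of 12 smooth muscle markers, 6 were higher, 0 lower and 6 not past, with the same counts adjusted over the list alone (adjusted p = 0.00601, and adjusted p = 0.0714 with an estimated correlation). TAGLN was 4.83-fold, CNN1 at least 1.83-fold and ACTA2 1.90-fold higher, but ACTA2 did not pass with the mean of its probe sets (adjusted p = 0.974). Of 10 pericyte markers, 4 were higher, 1 lower and 5 not past, also adjusted over the list alone (adjusted p = 0.218), with NOTCH3 at least 4.03-fold, PDGFRB at least 2.77-fold and CSPG4 at least 1.60-fold higher. NOTCH3 was above the floor on 3 of 6 and PDGFRB on 2 of 6 dermal-labelled arrays.

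The TGF-beta, mesenchymal transition and junction lists did not pass as groups by camera. Of 29 TGF-beta and BMP genes, 16 were higher, 7 lower and 6 not past, also adjusted over the list alone (adjusted p = 0.0608), with the activin subunit INHBA 20.1-fold and the BMP antagonist GREM1 at least 5.03-fold higher. Of 19 mesenchymal transition genes, 11 were higher, 5 lower and 3 not past, also adjusted over the list alone (adjusted p = 0.0608). The transcription factor SNAI2 was at least 7.01-fold higher, and POSTN, also in this list, was lower. Of 26 junction genes, 9 were higher, 13 lower and 4 not past; adjusted over the list alone, 11 were higher and 14 lower (adjusted p = 0.17), with PCDH10 49.4-fold lower, CLDN1 17.2-fold higher and CDH2 4.38-fold higher. Axon guidance and Eph genes included 14 higher, 7 lower and 7 not past of 28; adjusted over the list alone, 15 were higher and 7 lower. That list passed at the preset correlation (adjusted p = 0.0415) but not with an estimated correlation (adjusted p = 0.0705), without aortic 1 (adjusted p = 0.057) or without aortic 3 (adjusted p = 0.0522), and SEMA3A was at least 6.84-fold higher.

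Genes that recruit leukocytes were higher in aortic-labelled cells. Of 26 leukocyte adhesion and chemokine genes, 19 were higher, 3 lower and 4 not past, with the same 19 and 3 adjusted over the list alone (list median 1.10, adjusted p = 6.98e-08). CXCL11 stood at 11.3 ± 0.0829 against 8.10 ± 0.129 (8.96-fold, adjusted p = 3.39e-11; SD, n = 6 each), and CX3CL1 was 8.91-fold higher. The interferon response list did not move as a group, with 8 higher, 7 lower and 9 not past of 24, and 9 and 7 adjusted over the list alone (adjusted p = 0.992). Its median of 0.06 and its mean of -0.10 had opposite signs, and the median turned negative with arrays centred on their median. Its member BST2 was 14.7-fold lower in aortic-labelled cells, OAS2 1.64-fold lower and GBP1 1.55-fold higher. Of 18 MHC and antigen presentation genes, 4 were higher, 6 lower and 8 not past; adjusted over the list alone, 5 were higher and 6 lower (adjusted p = 0.206). HLA-DPA1 was 4.22-fold and HLA-DPB1 1.61-fold lower, whereas CD74 was at least 2.32-fold higher with overlapping groups, above the floor on 3 of 6 dermal-labelled arrays. With the mean of their probe sets, HLA-DPB1 and CD74 did not pass (adjusted p = 0.596 and 0.252).

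Cell cycle genes were lower in aortic-labelled cells, in 31 of 32 members with 0 higher, also adjusted over the list alone. The list median was -1.29 (camera adjusted p = 2.44e-27 at the preset correlation and 0.000261 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, stood at 10.1 ± 0.0865 against 12.4 ± 0.0576 (5.18-fold, adjusted p = 3.39e-11; SD, n = 6 each). BIRC5 was 4.18-fold, CDC20 3.86-fold and the proliferation marker MKI67 2.40-fold lower. The list median was -1.30 without dermal 5 and 6, the samples with the highest actin ratios. Of 18 senescence and growth arrest genes, 13 were higher, 4 lower and 1 not past, also adjusted over the list alone (list median 0.57, adjusted p = 0.00601). IGFBP5 was at least 4.61-fold higher, which did not pass with the mean of its probe sets (adjusted p = 0.0618), whereas the collagenase MMP1, a secreted protein of senescent cells, was 9.35-fold lower. Of 14 cholesterol synthesis genes, 10 were lower, 0 higher and 4 not past; adjusted over the list alone, 11 were lower (list median -0.65, adjusted p = 8.56e-08). INSIG1 was 2.94-fold, HMGCS1 2.89-fold and MSMO1 2.29-fold lower. Of 26 fatty acid and lipoprotein genes, 14 were higher, 6 lower and 6 not past; adjusted over the list alone, 15 were higher and 6 lower (list median 0.54, adjusted p = 0.00519). The lipid-sensing receptor PPARG was 6.85-fold, VLDLR 7.12-fold and the lipase inhibitor ANGPTL4 3.57-fold higher. Glycolysis and hypoxia genes included 14 higher, 2 lower and 11 not past of 27; adjusted over the list alone, 15 were higher and 2 lower. This list passed at the preset correlation (list median 0.19, adjusted p = 0.0171) but not with an estimated correlation (adjusted p = 0.242), with VEGFA 2.73-fold, ALDOC 1.86-fold and P4HA1 1.84-fold higher.

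The remaining vascular lists held members in both directions. Of 24 vascular tone and flow genes, 10 were higher, 10 lower and 4 not past, also adjusted over the list alone. The list median of 0.10 and the list test had opposite signs (adjusted p = 0.6251), and the median turned negative with arrays centred on their median. The cyclooxygenase PTGS1 was 7.45-fold lower in aortic-labelled cells, and the endothelin receptor EDNRB was 4.24-fold higher. GUCY1A1 was above the floor on 2 of 6 aortic-labelled and 1 of 6 dermal-labelled arrays, with both group means under the floor, so no fold is given. Of 20 coagulation and fibrinolysis genes, 6 were higher, 10 lower and 4 not past, also adjusted over the list alone (list median -0.32, adjusted p = 0.0608). Thrombomodulin, THBD, an anticoagulant receptor, stood at 10.5 ± 0.0344 against 12.4 ± 0.0487 (3.74-fold lower, adjusted p = 2.21e-11; SD, n = 6 each), SERPIND1 was 2.50-fold lower and the plasminogen activator PLAU 3.06-fold higher. Of 26 angiogenic genes, 13 were higher, 10 lower and 3 not past, also adjusted over the list alone (adjusted p = 0.759). For immediate early and dissociation stress genes, 5 were higher, 7 lower and 5 not past of 17; adjusted over the list alone, 6 were higher and 7 lower (adjusted p = 0.801). ATF3 was 1.95-fold and DUSP1 1.57-fold higher, and IER2 1.63-fold lower. For the unfolded protein response, 8 were higher, 6 lower and 6 not past of 20; adjusted over the list alone, 8 were higher and 7 lower. That list's median of -0.06 and its mean of 0.26 had opposite signs (adjusted p = 0.992), with CHAC1 3.32-fold and ASNS 2.08-fold higher. CHAC1 was above the floor on 4 of 6 dermal-labelled arrays, and ASNS did not pass with the mean of its probe sets (adjusted p = 0.206).

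The lists of keratinocyte, melanocyte, leukocyte and adipocyte markers did not pass by camera. Of 11 keratinocyte markers, 3 were higher, 1 lower and 7 not past, also adjusted over the list alone (adjusted p = 0.647); the list median of -0.03 and mean of 0.76 had opposite signs, the mean being set by DSP. PERP was 1.57-fold and KRT15 at least 1.78-fold higher, KRT15 with overlapping groups and 1 of 6 dermal-labelled arrays above the floor. KRT15 did not pass after quantile normalization (adjusted p = 0.0548) or without aortic 1, 2 or 5 (adjusted p = 0.0563 to 0.0581). Of 8 melanocyte markers, 3 were higher, 0 lower and 5 not past, also adjusted over the list alone (adjusted p = 0.144), namely EDNRB, MITF (1.65-fold) and TYRP1 (both group means under the floor, with overlapping groups). MITF did not pass with the mean of its probe sets (adjusted p = 0.654). TYRP1 was above the floor on 3 aortic-labelled arrays and 1 dermal-labelled array. It did not pass after quantile normalization (adjusted p = 0.156), with arrays centred (adjusted p = 0.0687) or without aortic 1, 2, 4, 5 or 6 or dermal 6 (adjusted p = 0.053 to 0.0702). Of 14 leukocyte markers, 2 were higher, 0 lower and 12 not past, also adjusted over the list alone (adjusted p = 0.204). These were LAPTM5, 3.06-fold higher, and ITGAX, at least 2.15-fold higher. The leukocyte antigen PTPRC stood at 3.64 ± 1.65 against 4.17 ± 0.905, above the floor on 1 of 6 arrays in each group. Of 9 adipocyte markers, 3 were higher, 0 lower and 6 not past, also adjusted over the list alone (adjusted p = 0.0608), namely FABP4, PPARG and LPL (at least 2.14-fold), all of which are in other lists too. LPL was above the floor on 2 of 6 dermal-labelled arrays and did not pass with the mean of its probe sets (adjusted p = 0.111).

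**Figure D3:**
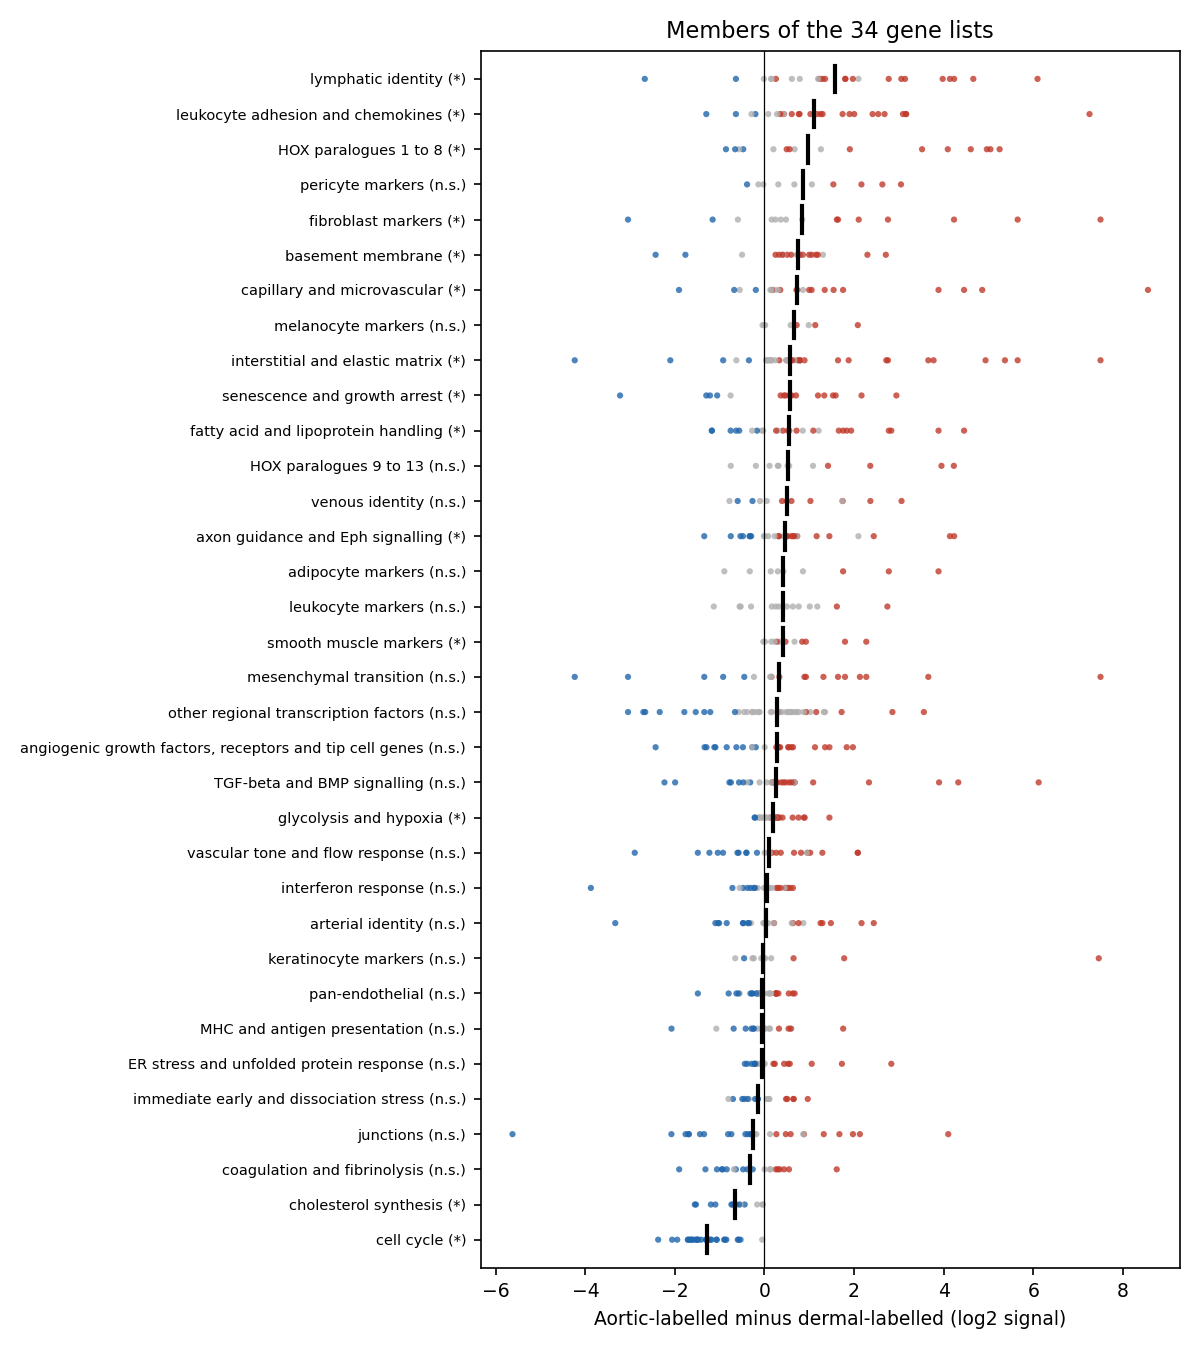
Difference between group means (aortic-labelled minus dermal-labelled, log2, horizontal) of each member of the 34 gene lists (vertical), red where higher and blue where lower past the adjusted threshold, grey otherwise; black ticks are list medians and * marks lists with a camera adjusted p under 0.05. The lymphatic list has the highest median, 1.58, and the cell cycle list the lowest, -1.29.

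In all, 14 of the 34 lists passed at the preset correlation, 12 higher and 2 lower in aortic-labelled cells. With an estimated correlation 10 passed, all of them among the 14, and the fibroblast, smooth muscle, axon guidance and glycolysis lists did not. With values on all arrays raised to 1 common floor, the highest of the 12, 9 of the named genes no longer passed: ACKR1, CPE, GUCY1A1, CNN1, CSPG4, KRT15, TYRP1, ITGAX and LPL (adjusted p = 0.0545 to 1).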

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

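Within each group of 6 samples, the highest and the lowest value were set against the others by Dixon's ratio. This was done for every list mean and array measure. A named gene was checked in a group only where all 6 arrays of that group were above the floor, so samples far from the rest in dimmer genes were not looked for. Of 255 groups of values tested, 18 held a sample far from the rest, where chance alone gives 1 in 20, or 12.8. No flag repeats a group difference, and none was weighed further.

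Among the aortic-labelled samples, 7 genes had such a sample. MEOX2 was highest in aortic 2, at a log2 signal of 9.906, and PCDH10 in aortic 1, at 7.052. HOXD9 was highest in aortic 4, at 9.245. Aortic 5 was lowest for IGFBP3, at 10.19, and for HLA-DPA1, at 7.55. PLAU was lowest in aortic 2, at 11.43, and IGFBP5 in aortic 3, at 6.318. The median signal of the array was highest for aortic 2, at 97.74 with the nearest other array at 84.86, and the mean of the keratinocyte markers was highest there too, at 7.222.

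Among the dermal-labelled samples, 5 genes were involved. VIPR1 was lowest in dermal 3, at 8.11, and ACTA2 in dermal 5, at 9.532. Dermal 4 had the lowest NOS3, at 8.806, and the highest ENG, at 12.63. DUSP1 was highest in dermal 2, at 13.27. Of the list means, dermal 3 was highest for glycolysis and hypoxia, at 11.05, and for the other regional transcription factors, at 5.629. Dermal 4 was highest for lymphatic identity, at 7.07, and dermal 5 lowest for senescence and growth arrest, at 10.43. In the 7 genes of the aortic-labelled and the 5 genes of the dermal-labelled samples, the 2 groups still did not overlap.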

How the results depend on the processing

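Raising values to each array's floor or to 1 common floor (the highest of the 12), log2 of the signal plus 32 and leaving out dermal 5 and 6 were chosen after seeing the data. Of the 14 lists past the threshold, 8 stayed past it in the same direction in all 26 alternatives: lymphatic, capillary, leukocyte adhesion, basement membrane, interstitial matrix, fatty acid, cholesterol synthesis and cell cycle. HOX paralogues 1 to 8 did not pass among genes above the median (highest adjusted p = 0.0696), nor senescence with the mean of probe sets (0.0513). The axon guidance list passed in 18 and the glycolysis list in 22 of 26. Of the 20 lists not past, 9 passed in some alternative. The 26 alternatives leave out fry, used here as a directional test. It asks whether a list's members shift in 1 direction, not whether they differ more than other genes. Many lists that did not pass by camera passed by fry, among them the arterial (fry adjusted p = 4.43e-06) and junction lists (fry adjusted p = 4.75e-10). The interferon (fry adjusted p = 0.0579) and angiogenic lists (fry adjusted p = 0.1875) did not pass by this directional test either. With members allowed to go both ways, both lists passed (mixed fry adjusted p = 4.12e-14 and 4.53e-16). Signal over background limits what can be seen, and dim genes passed less often at 6 arrays per group. In the main setting 1004 genes were higher and 607 lower by 2-fold or more. With only genes above the median of mean signal tested, 324 were higher and 362 lower by this fold. The excess of higher genes at 2-fold was thus not seen among the brighter genes.

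The count of 7160 genes became 14119 with every probe set tested on its own (8105 higher, 6014 lower; 2475 and 1289 by 2-fold or more), 1388 against a fold of 1.5 (767 higher, 621 lower; 649 higher by 2-fold or more), 3585 with numbers 1 to 3 alone (1906 higher, 1679 lower) and 4019 with numbers 4 to 6 alone (2054 higher, 1965 lower). More features, a stricter question and fewer samples account for these. Raising values to the floor gave 11383 genes, 7884 of them higher, and the aortic-labelled arrays have the higher floors. Centring arrays on their median left 2303 genes higher, since it lowers that group by the difference of medians. Log2 of the signal plus 32 and the common floor left 601 and 604 genes higher by 2-fold or more, because they shrink differences of dim genes. Without dermal 5 and 6, 6390 genes passed. Leaving out each sample in turn gave 6777 to 6971 genes, 3540 to 3718 higher and 3229 to 3322 lower, 931 to 1064 and 585 to 618 by 2-fold or more, and 13 to 15 lists.

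With the replicate number as a block, 6611 genes passed, 6313 of them among the 7160, and 13 lists. The calls of CPE and KRT15 (adjusted p = 0.0796 and 0.0795) and of the axon guidance list (adjusted p = 0.0663) ended, and no other call of a named gene or list changed. The numbers were not taken to pair the samples: same-numbered samples' deviations from their group means correlated at -0.0357 to 0.234, over 0.1 for 4 of 6 numbers, and 3 of 6 correlated best with their own number.

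No named gene or list that changed sign passed the threshold in that alternative; the cause was not tested. Over all genes, 35 with the mean of probe sets and 26 with values raised to each array's floor were called in both fits with opposite signs. With the mean of probe sets, PECAM1 stood at -0.0214, PTPRC at 0.257, the immediate early list at 0.061 and the keratinocyte list at 0.0175. PECAM1 and PTPRC each have a probe set past the threshold in the opposite direction. After quantile normalization the pan-endothelial list stood at 0.0137 and the arterial list at -0.0197. With arrays centred, EFNB2 stood at -0.0792, and the arterial, interferon and vascular tone lists at -0.127, -0.105 and -0.0652. Among genes above the median, the arterial list stood at -0.0205, other regional transcription factors at -0.185, vascular tone at -0.0814, coagulation at 0.0022, immediate early at 0.0505 and keratinocyte markers at 0.15. Keratinocyte markers stood at 0.3997 above the 25th percentile, at 0.244 with numbers 1 to 3 and 0.0506 with numbers 4 to 6. The unfolded protein response list stood at 0.00205 with numbers 1 to 3. At the floor, PTPRC stood at 0.404, the MHC list at 0.00347 and keratinocyte markers at 0.389. At the common floor, the arterial list stood at -0.0205 and keratinocyte markers at 0.0627. Leaving out each sample in turn, the arterial list ranged from -0.0145 to 0.0921 and the keratinocyte list from -0.226 to 0.166.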

Other observations

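The genes in this paragraph and the next were chosen after their values were seen. The list of other regional transcription factors did not pass as a group by camera, but 9 of its members were higher in dermal-labelled cells. Among them GATA4, a factor of heart development, stood at a log2 signal of 7.85 ± 0.0535 against 5.14 ± 1.45 in aortic-labelled cells (at least 3.77-fold, adjusted p = 0.00255 by limma; SD, n = 6 each), with 4 of 6 aortic-labelled arrays above the floor. GATA6 was 3.46-fold higher (adjusted p = 3.32e-10) and TBX18 at least 2.63-fold (adjusted p = 4.31e-05, 3 of 6 aortic-labelled arrays above the floor). The HOX cofactor MEIS1, not in the list, was at least 13.5-fold higher (adjusted p = 5.02e-06, 1 of 6). GATA3, also outside the list, was 6.95-fold higher (adjusted p = 5.05e-12). The water channel AQP1 was 3.76-fold higher in dermal-labelled cells (adjusted p = 2.52e-08). AQP1 belongs to the capillary and microvascular list, as 1 of its 3 members that were lower in aortic-labelled cells. HAND2-AS1 was at least 2.33-fold higher, with aortic-labelled arrays all at background. For each of these genes, the groups did not overlap.

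MEG3 belongs to an imprinted cluster of noncoding RNAs. Its neighbour SNORD114-3 was at least 16.9-fold higher in aortic-labelled cells (adjusted p = 4.2e-06), and MEG9 was at least 3.16-fold higher (adjusted p = 0.00269) with 3 of 6 dermal-labelled arrays above the floor.

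The tests of signals at the background, of exchanged labels, of fibroblasts and of neighbouring genes were chosen after the results they bear on were seen. Genes along the chromosomes of the GRCh38.p14 annotation were scanned in windows of 8 for genes at least 4-fold higher in deposited signals, background included, of which there were 330 among 18984. The fullest window ran from HOXD10 to HAGLROS, with 8 of 8 genes, where the fullest window in 1000 shuffles of gene order held 5 (permutation p = 0.001, the smallest that 1000 shuffles can give). A window from PSG1 to PSG9 held 5 of 8 (permutation p = 0.002), but these paralogues are nearly identical and their probe sets may share signal. For genes at least 4-fold lower, the fullest window held 3 of 8, at HAND2 (permutation p = 0.122). Several HOXD genes had already been seen to be higher and these genes lie together, so the scan was likely to return this window. The window also holds HOXD-AS2, HAGLR and HAGLROS beside the HOXD genes, which the shuffles treat as separate genes. The scan says nothing of the mechanism.

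Of 100 splits of the 12 samples into 6 and 6, 1 gave as many as 7160 genes, the real split, and the highest other gave 2. The real grouping thus stood apart from the other splits drawn. Every other split mixes the 2 groups, so the difference between them adds to the spread, and the 2 is not a count expected by chance. As the samples of a group may be technical repeats, the splits cannot speak to chance differences between cultures.

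The pattern most worth following up is the higher lymphatic and capillary lists in aortic-labelled cells, while 8 arterial genes, among them SEMA3G and IGFBP3, were higher there and 9, among them HEY2, were lower. Signals at the background are argued against, since 26 of the 28 members called higher stayed so with values on all arrays raised to the highest of the 12 floors. A lymphatic programme in the aortic-labelled cells was tested with a second list of 17 measured genes whose values had not been looked at; 7 were higher and 1 lower, with a median of 0.20 and a camera p of 0.0603, which leaves it open. Exchanged group labels could give the pattern too, and would raise the arterial list in the dermal-labelled samples, but that list's camera p was 0.992 with members going both ways, so an exchange cannot be told apart from a difference between the cultures. A true difference between the named tissues, and cells of another origin than named in either group, also stay open.

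A second pattern is the higher collagen and matrix genes in aortic-labelled cells, with COL1A1 at a log2 difference of 7.50. Fibroblasts in the cultures stay open. Of 2 genes abundant in fibroblasts, LUM was under the mean floor in both groups and decides nothing; DCN stood at 6.55 ± 0.389 against 6.30 ± 0.507 (SD, n = 6 each; upper 95% limit of the difference 0.794), but is a single gene. Of 15 fibroblast markers, 7 were higher, and 8 of the 15 are in other lists. Smooth muscle cells were not excluded either, with 6 of 12 markers higher, and neither was a mesenchymal change of the endothelial cells themselves.

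Also weighed was the lower cell cycle list in aortic-labelled cells, with a median of -1.29. Without dermal 5 and 6, whose actin ratios were highest, the median was -1.30, so the difference did not rest on those samples. After quantile normalization the list median was -1.32. That step moved the median of all genes by only -0.1, so it could hardly have removed a difference of this size. It shows only that the list differed by far more than this rescaling moved the genes. Differences in confluence, passage or growth rate, for which the labels give no values per sample, may account for the lower list. A difference between the cell types may do so too, and the design does not separate these.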
